A study of Mus musculus with 4 samples.

How the data were processed

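Total RNA of cultured mouse aortic endothelial cells had been made into libraries with a TruSeq RNA kit, which does not mark strand, with 2 biological replicates per group, per the labels and the design text. The authors deposited 1 table of raw counts per gene, with 27179 rows named by Entrez gene identifiers and a column for each of the 4 libraries. The submitters' processing notes name STAR 2.5.2b, featureCounts, Subread 1.4.6-p1 and the mm10 build; their settings and the annotation release are not given in the sources used here, so how reads shared by several genes were counted is unknown. Of the rows, 7817 had 0 counts in all libraries. Identifiers were matched to RefSeq genes of the GRCm38.p6 assembly, the same build as mm10, from which symbols and coordinates were taken; 25275 matched. The 1904 unmatched rows held 6.31% of the counts and stayed in the library sizes and tests without a name.

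Library totals ranged from 13815695 to 18005840 counts, and CPM floors from these totals cover counting error only. Samples were grouped by the treatment label. Raw counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, total 15), libraries scaled by TMM (factors 0.987 to 1.01), and conditioned medium compared with control by the quasi-likelihood test without a replicate block, two-sided, with Benjamini-Hochberg adjustment over the 13897 genes tested. A gene was called at an adjusted p under 0.05. The fit had 2 residual degrees of freedom and a biological coefficient of variation of 3.58%. SEs are the absolute log2 fold change over the square root of the F statistic. CPM values are counts scaled to library size by TMM, given as mean ± SD of 2 libraries.

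The tests, the alternatives, 28 pathway lists and 6 cell type marker lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists that qualified; camera with an estimated correlation and fry (limma 3.58.1) were the alternatives. Of 604 listed genes 602 had a row. Named genes are the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in the higher group, non-overlapping groups and a symbol, which passed over 1 unmatched gene in each direction; the 3 called members of each list with the largest absolute log2 fold change, or the member with the smallest p where none was called; and 14 genes always given (Tnf, Vcam1, Icam1, Sele, Ccl2, Cxcl10, Il6, Nfkbia, Tnfaip3, Nos3, Klf2, Cdh5, Pecam1 and Cd68). Cxcl12, Irf1, Irf8, Isg20, Cav1, Timp1, Timp3 and Cdkn1a were named from the lists after their values were seen, and the alternatives were run on them too. Some genes that meet the rule are not reported here by name and stay in the counts.

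Alternatives were RLE, upper-quartile and library-total scaling, no filter or at least 1 CPM in 2 libraries, a replicate block, a robust estimate of the spread, each library left out in turn (the lone library then assumed to vary like the other group), DESeq2 1.42.0, limma-voom and, for the 2-fold count, glmTreat against a fold of 1.2. Counts thinned to the smallest library total and the table without unmatched rows were added after the data were seen. The procedure was tested on simulated data for this comparison, on 13788 genes with the real means and depths. Their spread followed the fitted trend with mean count and was the same in both groups. The real control and treated pairs differed in spread, so the rates may not hold for them. The procedure recovered 60% of genes changed by 1.25-fold, 74% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. Of its calls 3.55% were false. With no gene changed it called 0 genes, and 4.83% lay at an unadjusted p under 0.05. A simulated list of 25 genes moved by 1.25-fold was called and 0 of 28 unmoved lists were. The moved list was drawn from genes with a mean of at least 100 counts, so it does not cover lists of low-count genes. The simulated genes varied independently of each other, so this could not test the preset correlation. In the real data the estimated correlations of the lists ran from -0.07 to 0.56. The highest was that of the type I interferon-stimulated list, and the glycolysis and hypoxia list had 0.29. Genes with a near-identical copy, overlapping genes and antisense partners are uncertain, since the counting could split or join their reads.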

Results

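Murine aortic endothelial cells of the mAEC line, a cultured model of the inner lining of large arteries, were profiled by RNA sequencing in 2 groups. The control group was kept in ordinary medium. The conditioned medium group received the culture supernatant of macrophages positive for TNFα, an inflammatory cytokine, and for CD68, a macrophage marker. Each group held 2 libraries, which the series describes as biological replicates. The deposited gene counts summed to 14966911 and 14493674 in the control libraries and to 13815695 and 18005840 in the conditioned medium libraries. At these depths 3 counts equalled between 0.166 and 0.217 CPM, a normalized count scaled to library size, and between 17338 and 17753 genes had at least 1 count per library.

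The control libraries differed from each other more than the conditioned medium libraries did. Over well-counted genes the SD of the log2 ratio was 0.11 within the control pair and 0.07 within the conditioned medium pair, against 0.18 to 0.19 between libraries of different groups. Both pairs differed beyond counting noise, with a chi-square per degree of freedom of 4.74 for the controls and 1.52 for the treated libraries. Each library was kept as a separate replicate, as the series describes them. The excess over counting noise cannot tell separate cultures from separate preparations of the same culture, so the spread behind the p-values could be of either kind. Whether the groups were cultured, prepared or sequenced in a single batch is not given in the sources used here, so a batch that follows the groups would enter each difference between them. Mitochondrial genes took 4.68% and 4.42% of the control counts and 4.21% and 4.25% of the conditioned medium counts.

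The comparison asked how the endothelial transcriptome differed after exposure to the macrophage supernatant. Of 28 type I interferon-stimulated genes 20 fell in conditioned medium, among them Ifit3, an antiviral effector (2.17-fold lower), and of 27 glycolysis and hypoxia genes 22 rose, among them Hk2, which encodes hexokinase (1.60-fold), and Slc2a1, the main glucose transporter (1.54-fold). Both groups were called by camera (adjusted p = 1.27e-24 and 9.95e-23), and neither was with an estimated correlation (adjusted p = 0.346 each with an estimated correlation). The chemokine genes Ccl2 and Cxcl10 fell 1.36-fold and 1.56-fold, the vascular selectin genes Sele and Selp rose 1.59-fold and 1.46-fold, and Vcam1, an adhesion receptor for leukocytes, had a fold change of 1.01 and was not called. Edn1, which encodes the vasoconstrictor peptide endothelin, fell 3.16-fold, and S100a8, an inflammatory calcium-binding protein, rose 4.02-fold. Most differences were small: 85.6% of the genes called changed by less than 1.5-fold, and their median absolute log2 fold change was 0.29.

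Of 13897 genes tested by edgeR's quasi-likelihood test, two-sided, 2330 passed an adjusted p of 0.05, 1186 of them higher and 1144 lower in conditioned medium. Of these, 138 changed by 2-fold or more, 112 higher and 26 lower. In 2329 of the 2330 the libraries of the 2 groups did not overlap in CPM, as in 57.2% of all tested genes, where 33.3% would separate by chance. DESeq2 called 868 genes, 44 of them by 2-fold or more. Without conditioned medium replicate 1 the test called 808 genes and without conditioned medium replicate 2 it called 569, with 86 and 63 by 2-fold or more, the spread then coming from the control pair alone.

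Among genes with a symbol and at least 5 CPM in the higher group, S100a8 rose most, from 9.83 ± 4.50 to 39.4 ± 2.36 CPM (mean ± SD, n = 2), a log2 fold change of 2.01 ± 0.15 (SE; edgeR adjusted p = 1.41e-08). It lies on chromosome 3, 90669071 to 90670034, in mm10. Its control libraries held 192 and 97 counts, and with a robust estimate of the spread it was not called (adjusted p = 0.0665, against 1.91e-86 at the lowest of its 15 alternatives). Next came Cstdc4, a stefin family gene at 1.87 ± 0.25, Cxcr2, a receptor for neutrophil-attracting chemokines, at 1.83 ± 0.13 (edgeR adjusted p = 5.30e-09), and Mmp3, a matrix-degrading protease, at 1.76 ± 0.16 (edgeR adjusted p = 1.72e-07). Prkcb, a protein kinase C gene, followed at 1.65 ± 0.20, Inhbb, an activin subunit, at 1.49 ± 0.15, Sapcd1 at 1.44 ± 0.19, Pglyrp1, which binds bacterial peptidoglycan, at 1.43 ± 0.09, Stc1, a secreted glycoprotein, at 1.41 ± 0.17, and Emilin2, an extracellular matrix protein, rose 2.64-fold. An unmatched gene without a symbol, at 1.78 ± 0.27, would stand among these and another, at -1.15 ± 0.13, among the falls. Cstdc4 has near-identical neighbours, so its counts are uncertain.

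Among the same genes Edn1 fell most, from 12.2 ± 2.21 to 3.86 ± 0.0508 CPM, a log2 fold change of -1.66 ± 0.17 (edgeR adjusted p = 8.72e-07). It lies on chromosome 13, 42301476 to 42307990, in mm10. Sult1a1, a sulfotransferase, followed at -1.37 ± 0.18, and Akr1c14, an aldo-keto reductase, at -1.12 ± 0.15. Of the other genes with the steepest falls, 5 were interferon-inducible: Gbp3 at -1.22 ± 0.10, Gbp5 at -1.13 ± 0.17, Ifit3 at -1.12 ± 0.11, and Tgtp2 and Tgtp1 at -1.04 ± 0.16 and -0.98 ± 0.15. Tgtp1 and Tgtp2 are near-identical copies, with 171, 166, 68 and 118 counts and 169, 173, 63 and 118 counts. The counting could split their reads between them or count the same reads for both. Each value is thus uncertain, and the 2 falls may be 1 signal. Cd300lg, a receptor of vascular endothelium, fell from 23.3 ± 2.92 to 11.8 ± 2.01 CPM (edgeR adjusted p = 7.91e-06). Gm4924, a predicted gene, with counts of 82 and 65 in control against 47 and 32, fell to 2.58 ± 1.14 CPM (edgeR adjusted p = 0.00936), but without conditioned medium replicate 2 its log2 fold change was -0.56 and it was not called (adjusted p = 0.298, its alternatives running from 2.13e-04).

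**Figure D1:**
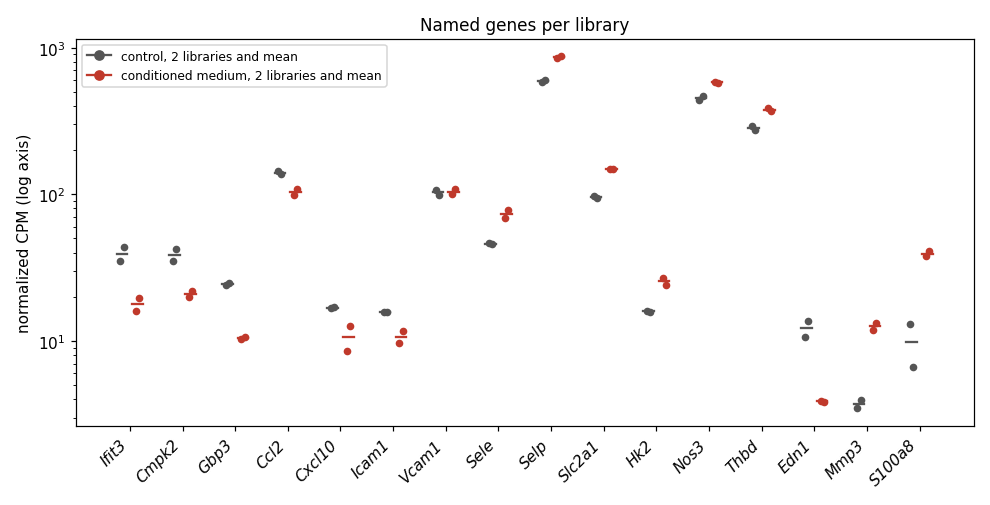
CPM of the named genes, on a log axis, with the 2 libraries of each group as points and their mean as a line. Gbp3 and Edn1 lie lower in conditioned medium and Slc2a1 and S100a8 higher, with no overlap between the groups, while the points of Vcam1 overlap.

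The type I interferon-stimulated list was called lower. Of 28 members tested, 20 fell and 1 rose, 22 and 1 when adjusted over the list alone, with a median log2 fold change of -0.48 (camera adjusted p = 1.27e-24; adjusted p = 0.346 with an estimated correlation). The steepest falls were in Ifit3 (-1.12 ± 0.11), its neighbour Ifit3b (-0.92 ± 0.11), with which it can share reads, and Cmpk2, a mitochondrial nucleotide kinase (-0.88 ± 0.09). Cmpk2 went from 38.6 ± 5.20 to 20.9 ± 1.31 CPM. The member that rose was Isg20, an exonuclease, at 0.57 ± 0.16. Interferon-inducible GTPases and IRF1 targets were also called lower as a list: 11 of 17 members fell and 1 rose, 13 and 1 when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 6.95e-12; adjusted p = 0.346 with an estimated correlation). Irf1, the transcription factor, was at -0.48 ± 0.10, and Irf8, a related factor, rose by 0.21 ± 0.05. The guanylate-binding protein genes share sequence with each other, so single members are less certain than the group. Isg20, Irf1 and Irf8 lost their calls without conditioned medium replicate 1 and in DESeq2, Isg20 and Irf8 also without replicate 2 of that group, and Isg20 without control replicate 2, where its log2 fold change was 0.35 (adjusted p over the alternatives: Isg20 (2.42e-04 to 0.237), Irf1 (2.39e-05 to 0.0697) and Irf8 (0.00213 to 0.170)).

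The MHC class I and antigen processing list was called lower. Of 19 members tested, 5 fell, 0 rose and 14 were not called, 6 and 0 when adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.00718; adjusted p = 0.571 with an estimated correlation). B2m, the shared light chain of class I molecules, fell from 979.8 ± 20.7 to 754 ± 27.0 CPM, a log2 fold change of -0.38 ± 0.04 (edgeR adjusted p = 3.80e-06). Erap1, which trims antigenic peptides, fell by 0.49 ± 0.08, and Psme2, a proteasome activator subunit, by 0.28 ± 0.07. The list's call was lost without control replicate 2, with a median of -0.01 and an adjusted p of 0.178, the highest of 13 alternatives that reached down to 1.73e-05, and the median was -0.19 without control replicate 1 and -0.13 without conditioned medium replicate 2. Psme2 lost its call in DESeq2 and without either conditioned medium library (adjusted p = 0.0821 and 0.168, its alternatives running from 0.00346 to 0.181).

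Genes that recruit and bind leukocytes divided. Among chemokines, 4 of 9 tested fell and 1 rose, 5 and 1 when adjusted over the list alone, with a median of -0.44 (camera adjusted p = 2.05e-04; adjusted p = 0.376 with an estimated correlation). Ccl2, a monocyte attractant, fell from 141 ± 4.07 to 103 ± 6.35 CPM (log2 fold change -0.44 ± 0.05; edgeR adjusted p = 5.49e-06). Cxcl1, a neutrophil attractant, was at -0.51 ± 0.07, Cxcl12 at -0.46 ± 0.06 and the interferon-inducible Cxcl10 at -0.64 ± 0.14 (edgeR adjusted p = 0.00281). Ccl4 rose by 1.54 ± 0.51 on 5 and 4 control counts against 11 and 18 treated counts, and DESeq2 gave it no adjusted p. Of 11 leukocyte adhesion molecules, 4 rose and 1 fell, 5 and 1 when adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.00109; adjusted p = 0.346 with an estimated correlation). Selp went from 592 ± 13.3 to 863 ± 15.5 CPM and Sele from 46.2 ± 0.383 to 73.1 ± 6.37 CPM, log2 fold changes of 0.54 ± 0.04 and 0.67 ± 0.07. Icam1, a ligand of leukocyte integrins, fell by 0.55 ± 0.12 (edgeR adjusted p = 0.00284), while Vcam1 stood at 103 ± 5.21 and 104 ± 5.66 CPM (edgeR adjusted p = 0.915). The chemokine median was -0.22 without control replicate 2, and Cxcl10 was at -0.41 without conditioned medium replicate 1 and -0.98 without replicate 2. Without conditioned medium replicate 1, Cxcl10 and Icam1 lost their calls, Icam1 also in DESeq2 (adjusted p = 0.102 and 0.0906, with alternatives down to 2.10e-06 and 1.25e-04). Ccl4 lost its call with no count filter (edgeR adjusted p = 0.0898) and with thinned counts (0.0534), with alternatives down to 0.0212. It also lost the call without any 1 of the 4 libraries, at log2 fold changes of 1.35 to 1.70.

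The list of NF-kB feedback and TNF signalling genes, targets and components of the pathway that TNFα activates, was not called: 4 of 25 members rose and 2 fell, 5 and 5 when adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.938). Bcl3, an atypical IκB protein, rose by 0.76 ± 0.15, Tnfrsf1b, a TNF receptor, by 0.36 ± 0.07 and Nfkbia, the feedback inhibitor IκBα, by 0.15 ± 0.04 (edgeR adjusted p = 0.0249), whereas Tnip1, a negative regulator, fell by 0.44 ± 0.06. Tnfaip3, encoding the inhibitor A20, stood at 7.05 ± 0.478 and 7.91 ± 1.68 CPM (edgeR adjusted p = 0.498), and Il6 at 1.98 ± 0.593 and 1.55 ± 0.556 CPM (edgeR adjusted p = 0.580). Tnf held 1 count in each group and was below the count filter. Cytokines and colony-stimulating factors showed 1 rise, Tnfsf9 (0.59 ± 0.17), and 1 fall, Csf1 (-0.30 ± 0.06), among 9 tested, the counts being 1 and 1 when adjusted over the list alone (median 0.12; camera adjusted p = 0.938). Of 10 complement and acute-phase genes 1 rose and 3 fell, 1 and 3 when adjusted over the list alone. Their median was -0.12, their mean 0.06 and the test pointed down (camera adjusted p = 0.123; 0.00579 without control replicate 1, 0.0391 with a filter at 1 CPM and 0.0298 with thinned counts, within alternatives of 0.00579 to 0.29). C3, the central complement component, fell from 173 ± 7.44 to 114 ± 6.31 CPM, C1ra was at -0.35 ± 0.11, and C4b at 1.90 ± 0.59 on 4 and 2 control counts against 12 and 13. DESeq2 gave C4b no adjusted p. Over the alternatives the adjusted p ranged past 0.05 for Tnfrsf1b (5.65e-06 to 0.0721), Nfkbia (0.00219 to 0.318), Tnfsf9 (0.00254 to 0.294), Csf1 (4.36e-07 to 0.0558), C1ra (1.88e-06 to 0.524) and C4b (0.00786 to 0.219), in each case without conditioned medium replicate 2, and also without replicate 1 of that group for all but Tnfrsf1b. Tnfsf9 and C4b also lost their calls without control replicate 1 (adjusted p = 0.118 and 0.0822), and C1ra and C4b without control replicate 2 (adjusted p = 0.524 and 0.219). C1ra, at -0.11 without that library and -0.55 without control replicate 1, was also not called by DESeq2, limma-voom, other scalings by upper quartile and library total, or with no count filter, nor were Tnfsf9 and Nfkbia by DESeq2, Tnfsf9 with thinned counts or C4b with no filter.

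The glycolysis and hypoxia response list was called higher. Of 27 tested, 22 rose and 0 fell, 23 and 0 when adjusted over the list alone, with a median log2 fold change of 0.30 (camera adjusted p = 9.95e-23; adjusted p = 0.346 with an estimated correlation). Slc2a1 went from 96.4 ± 2.33 to 149 ± 0.242 CPM (log2 fold change 0.63 ± 0.05; edgeR adjusted p = 2.06e-08), Hk2 rose by 0.68 ± 0.10, and Bnip3, a mitophagy receptor, by 0.57 ± 0.10. The cholesterol biosynthesis list was called higher, with 10 of 22 higher, 0 lower and 12 not called, 11 and 0 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 6.59e-08; adjusted p = 0.346 with an estimated correlation). Msmo1, a methylsterol monooxygenase, rose from 23.8 ± 0.114 to 36.4 ± 0.855 CPM (0.61 ± 0.08) and Mvd by 0.72 ± 0.17. Mvd lost its call in DESeq2 and without either conditioned medium library (adjusted p = 0.0749 and 0.0829, its alternatives running from 4.45e-05 to 0.0985).

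Nuclear-encoded oxidative phosphorylation genes were not called, with 2 of 25 higher, among them Cox7a2 (0.29 ± 0.08), 0 lower, and 2 and 0 when adjusted over the list alone. Their median was -0.02, their mean 0.03 and the test pointed up (camera adjusted p = 0.771). Among 18 NRF2 antioxidant genes 3 rose and 3 fell, 4 and 3 when adjusted over the list alone (median 0.03; camera adjusted p = 0.340). Hmox1, the heme-degrading enzyme, rose from 166 ± 0.593 to 255 ± 1.58 CPM (edgeR adjusted p = 6.99e-09), Nqo1 rose by 0.45 ± 0.09, and the cystine transporter gene Slc7a11 fell by 0.28 ± 0.05. The ATF4 amino-acid stress list had 2 rises, Cebpb (0.38 ± 0.09) and Ddit4 (0.31 ± 0.07), and 4 falls, led by Asns (-0.42 ± 0.07), among 18, with 2 and 4 when adjusted over the list alone (median -0.12; camera adjusted p = 0.220; 0.0272 without conditioned medium replicate 2, within alternatives of 0.0272 to 0.748). In the unfolded protein response 1 of 17 genes fell, Hspa5 (-0.13 ± 0.04), and 0 when adjusted over the list alone, with a median of -0.03, a mean of 0.02 and a test pointing up (camera adjusted p = 0.896). Without conditioned medium replicate 2, Cox7a2, Nqo1, Cebpb, Ddit4 and Hspa5 lost their calls, as did Slc7a11 and Hspa5 without replicate 1 of that group and Cox7a2 without control replicate 2 (log2 fold change 0.19), and Cebpb was at 0.14 without conditioned medium replicate 2. DESeq2 did not call Cox7a2, Cebpb, Ddit4 or Hspa5, the robust estimate Cebpb, and upper-quartile scaling or no count filter Hspa5. Over the alternatives their adjusted p ranged as follows: Cox7a2 (1.85e-05 to 0.296), Nqo1 (4.07e-11 to 0.110), Slc7a11 (2.48e-08 to 0.0861), Cebpb (1.90e-11 to 0.449), Ddit4 (4.66e-06 to 0.212) and Hspa5 (5.87e-04 to 0.432).

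Endothelial function genes changed in both directions. Of 11 vasoprotective and anticoagulant genes 6 rose and 1 fell, 8 and 1 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 2.05e-04; adjusted p = 0.346 with an estimated correlation). Nos3, the endothelial nitric oxide synthase, rose from 456 ± 19.3 to 580.5 ± 4.35 CPM (0.35 ± 0.04; edgeR adjusted p = 1.13e-05), Thbd, the anticoagulant receptor thrombomodulin, from 282 ± 12.8 to 377 ± 10.9 CPM (0.42 ± 0.05), and the flow-responsive factor gene Klf2 by 0.20 ± 0.05, while Cav1, a caveolar coat protein that binds nitric oxide synthase, fell by 0.33 ± 0.04. Ptgis, the prostacyclin synthase, was at 1.24 ± 0.37 on 8 and 14 control counts, and DESeq2 gave it no adjusted p. Coagulation and fibrinolysis genes moved both ways, 3 higher and 3 lower of 9, and 3 and 4 when adjusted over the list alone, with a median of 0.08, a mean of -0.02 and a test pointing down (camera adjusted p = 0.262). Thbs1, the matricellular protein thrombospondin, and the coagulation factor gene F8 fell by 0.66 ± 0.04 and 0.42 ± 0.05. Klf2 lost its call without either conditioned medium library (adjusted p = 0.127 and 0.0838, alternatives from 1.69e-04 to 0.127), and Ptgis with thinned counts and without either of them or control replicate 1 (adjusted p = 0.136, 0.213 and 0.215, alternatives from 0.00891 to 0.215).

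Of 16 angiogenesis and tip-cell genes 8 fell and 3 rose, 9 and 3 when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0411; adjusted p = 0.451 with an estimated correlation). Angpt2, a ligand that destabilises vessels, fell from 148 ± 2.92 to 83.5 ± 6.65 CPM (-0.83 ± 0.05; edgeR adjusted p = 3.00e-09), whereas the growth factor gene Vegfa rose by 0.58 ± 0.07 and the netrin receptor gene Unc5b by 0.42 ± 0.06. This list's call was lost in 4 of 13 alternatives. These were the other scalings by upper quartile (camera adjusted p = 0.0592) and library total (0.057), a replicate block (0.0715), and leaving out conditioned medium replicate 2 (median -0.16). The endothelial identity list was not called, 5 of 22 higher and 5 lower, 5 and 6 when adjusted over the list alone (median 0.02; camera adjusted p = 0.658). The junction and adhesion gene Pecam1 stood at 2415 ± 41.5 and 2417 ± 8.83 CPM and Cdh5, the endothelial cadherin, at 1909 ± 20.8 and 2001 ± 17.8 CPM (edgeR adjusted p = 0.994 and 0.295; Cdh5 reached 0.0273 without control replicate 2, within 0.0273 to 0.738). Flt1, a VEGF receptor, and Eng, a TGF-beta co-receptor, rose by 0.38 ± 0.04 and 0.32 ± 0.05, and Robo4 fell by 0.35 ± 0.05. Notch genes, 4 higher and 2 lower of 10 and 5 and 3 when adjusted over the list alone, included Notch1 (0.38 ± 0.05), its ligand gene Dll1 (0.39 ± 0.10) and the target Hes1 (-0.33 ± 0.06). That list had a median of 0.20 and was not called (camera adjusted p = 0.0771; 0.0257 without control replicate 2, within alternatives of 0.0257 to 0.198). Dll1 lost its call in DESeq2 and without either conditioned medium library (adjusted p = 0.0575 and 0.188, alternatives from 0.00374 to 0.193), and Hes1 without replicate 1 of that group (adjusted p = 0.0678, alternatives from 2.63e-06).

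The list of matrix proteases and inhibitors was called higher, with 7 members higher, 1 lower and 8 not called of 16, and 7 and 1 when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 9.47e-04; adjusted p = 0.346 with an estimated correlation). Mmp3 went from 3.71 ± 0.365 to 12.6 ± 1.04 CPM, Mmp10 rose by 1.28 ± 0.36, from 0.817 ± 0.187 to 1.97 ± 0.434 CPM, Adamts4, an aggrecan-cleaving protease, rose by 0.48 ± 0.05, the inhibitor gene Timp1 by 0.35 ± 0.11, and Timp3 fell by 0.20 ± 0.04. The other matrix and plasticity lists were not called. Collagens and matrix proteins had 2 higher and 1 lower of 14, 4 and 1 when adjusted over the list alone (median 0.02; camera adjusted p = 0.443), with the basement membrane gene Nid1 at 0.32 ± 0.04, Bgn at 0.56 ± 0.19 and Lamc1 at -0.15 ± 0.04. Endothelial-to-mesenchymal transition genes had 3 higher and 3 lower of 12, 3 and 5 when adjusted over the list alone, with a median of -0.05, a mean of 0.04 and a test pointing up (camera adjusted p = 0.835). S100a4 rose by 0.86 ± 0.08 and Snai1, a repressor of cadherin genes, by 0.48 ± 0.11, and Tgfb2 fell by 0.48 ± 0.07. In the TGF-beta and BMP response 4 of 15 rose and 3 fell, 4 and 4 when adjusted over the list alone (median 0.21; camera adjusted p = 0.715), Ccn2, a secreted matricellular protein, falling by 0.72 ± 0.04 and Id3 by 0.56 ± 0.14. Cell junction genes had 1 higher, Plvap (0.14 ± 0.04), and 2 lower, Jam3 (-0.36 ± 0.07) and Tjp1 (-0.20 ± 0.04), of 15, the counts being 1 and 2 when adjusted over the list alone (median 0.05; camera adjusted p = 0.950). Calls were lost for Mmp10, Timp1, Timp3, Bgn, Lamc1, Tjp1 and Plvap without either conditioned medium library, for Snai1 without replicate 2 and Id3 without replicate 1 of that group, for Bgn and Timp1 without control replicate 1 and for Mmp10 without control replicate 2. Bgn was at 0.32 and 0.85 without control replicates 1 and 2. DESeq2 did not call Timp1, Bgn, Snai1, Id3 or Plvap, and Bgn was also not called with library totals, no count filter or thinned counts. Mmp10 had no adjusted p in DESeq2. The adjusted p over the alternatives ranged as follows: Mmp10 (0.00449 to 0.280), Timp1 (0.0262 to 0.363), Timp3 (1.14e-10 to 0.140), Bgn (0.00183 to 0.370), Lamc1 (5.45e-06 to 0.375), Snai1 (1.16e-05 to 0.129), Id3 (4.75e-04 to 0.155), Tjp1 (4.65e-09 to 0.181) and Plvap (0.00149 to 0.347).

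**Figure D2:**
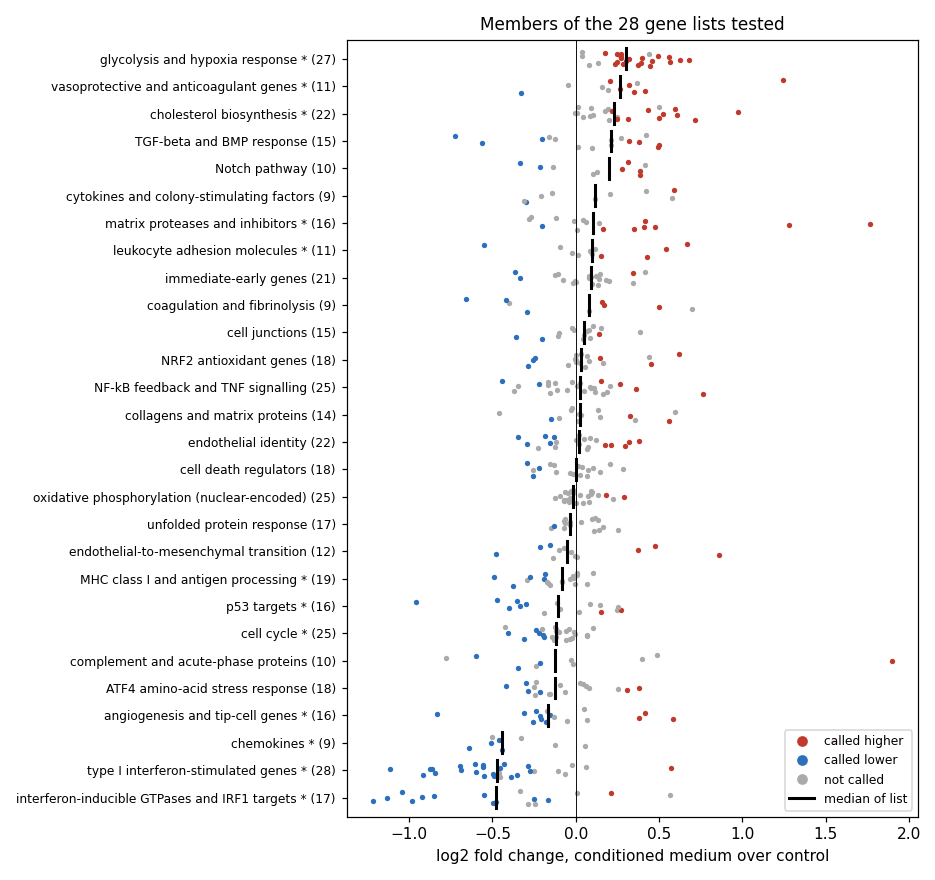
Log2 fold change, conditioned medium over control, of each tested member of the 28 gene lists, with red points called higher, blue points called lower, grey points not called and a black bar at the median of each list. Stars mark lists called with the preset correlation and numbers in parentheses give the members tested. The interferon lists lie to the left, with medians of -0.48, and the glycolysis and hypoxia list to the right, at 0.30.

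The cell cycle list was called lower. Of its 25 genes 6 fell, 0 rose and 19 were not called, 7 and 0 when adjusted over the list alone, with a median of -0.12 (camera adjusted p = 9.47e-04; adjusted p = 0.346 with an estimated correlation). The proliferation marker gene Mki67 fell from 692 ± 2.10 to 587 ± 0.298 CPM (-0.24 ± 0.04; edgeR adjusted p = 3.58e-04), and the cyclin genes Ccna2 and Ccne2 fell by 0.31 ± 0.05 and 0.41 ± 0.09. Of 16 p53 targets 6 fell and 2 rose, 6 and 3 when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.00718; adjusted p = 0.590 with an estimated correlation). Sesn1, a stress-induced metabolic regulator, fell from 31.3 ± 1.96 to 16.1 ± 0.247 CPM (-0.96 ± 0.09), Gadd45a by 0.47 ± 0.06 and the death receptor gene Fas by 0.40 ± 0.13, whereas Cdkn1a, the p21 cell cycle inhibitor, rose by 0.15 ± 0.05. Cell death regulators (0 higher and 3 lower of 18, and 0 and 3 when adjusted over the list alone; median -0.0013; camera adjusted p = 0.611) and immediate-early genes (1 higher and 2 lower of 21, and 1 and 2 when adjusted over the list alone; median 0.09; camera adjusted p = 0.567) were not called. The falls among the former included Bcl2 (-0.26 ± 0.06) and Casp8 (-0.22 ± 0.06). Among the latter, Dusp6 rose by 0.34 ± 0.05, and Klf6 and Egr1 fell by 0.37 ± 0.04 and 0.34 ± 0.09. The p53 list lost its call without conditioned medium replicate 1 (adjusted p = 0.106, alternatives from 0.00057), its median being -0.06 then and -0.16 without replicate 2. Mki67, Ccne2, Cdkn1a, Fas, Bcl2, Casp8 and Egr1 lost their calls without either conditioned medium library, Ccna2 without replicate 2, Fas also without control replicate 1 and Casp8 and Egr1 without control replicate 2. Cdkn1a was at 0.07 without conditioned medium replicate 2. DESeq2 did not call Ccne2, Cdkn1a, Fas, Bcl2, Casp8 or Egr1, nor were Cdkn1a and Fas called with no count filter or Cdkn1a with thinned counts. Over the alternatives the adjusted p ranged as follows: Mki67 (2.57e-11 to 0.0828), Ccna2 (1.23e-11 to 0.0572), Ccne2 (1.11e-05 to 0.0872), Cdkn1a (0.00189 to 0.607), Fas (0.0198 to 0.332), Bcl2 (2.25e-04 to 0.0957), Casp8 (0.00162 to 0.251) and Egr1 (5.01e-05 to 0.204).

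Of the 28 lists tested, 12 were called by camera with the preset correlation, 5 higher and 7 lower. With an estimated correlation camera called 0, with 2 lists at an unadjusted p under 0.05, and fry, which asks whether a list moves a single way on balance, called 2, the vasoprotective and the cholesterol lists (adjusted p = 0.0370 each). For the type I interferon-stimulated list fry gave an adjusted p of 0.116, and for the glycolysis and hypoxia list 0.0738.

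Markers of other cell types were few. Of 22 macrophage markers 4 passed the count filter and none was called by edgeR, nor were any at an unadjusted p under 0.05. Cd68, a lysosomal glycoprotein used to mark macrophages, was abundant in both groups, at 234 ± 20.0 and 245 ± 5.76 CPM (edgeR adjusted p = 0.429; 0.00251 without control replicate 2, within 0.00251 to 0.835), Lyz1 was at -0.62 ± 0.31 (edgeR adjusted p = 0.190), and the macrophage genes Adgre1, Tyrobp, C1qa and Spi1 had 0 counts in all 4 libraries. The median over the 4 was 0.02 and the mean -0.13. In the smooth muscle list 1 of 4 fell, Mylk (-0.32 ± 0.05), with a median of 0.03 and a mean of -0.02. In the fibroblast list 2 of 4 rose, Pi16 (0.32 ± 0.07) and Pdgfra (0.28 ± 0.08), with a median of 0.17. Among epithelial and mesothelial markers 2 of 3 rose, Krt19 (2.47 ± 0.28, from 0.818 ± 0.102 to 4.58 ± 0.0515 CPM) and Msln (0.29 ± 0.08), and 3 when adjusted over the list alone, with a median of 0.40. Of 4 lymphatic endothelial markers Pdpn rose (0.73 ± 0.13), with a median of 0.08. None of 8 lymphocyte markers passed the filter. For the macrophage, smooth muscle, fibroblast and lymphatic lists the counts were the same when adjusted over the list alone, and with under 5 members none of these lists was tested as a set. Msln lost its call without conditioned medium replicate 1 and Pi16 and Pdgfra without either treated library (adjusted p over the alternatives: Msln (0.00214 to 0.271), Pi16 (1.63e-04 to 0.117) and Pdgfra (0.00447 to 0.264)), Pdgfra also without control replicate 1 and DESeq2 called none of the 3.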

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

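Thinning the counts and dropping unmatched genes were chosen after the data were seen; the other settings were planned. The 2330 genes called kept their direction under each setting in which they had a value. Other scalings and filters called 1904 to 2363 genes, limma-voom 2325, the robust estimate 2497, thinned counts 2083 and the table without unmatched genes 2342. Left out in turn, the libraries gave 569 to 3107 calls, 323 to 1485 higher and 246 to 1622 lower, with 63 to 141 by 2-fold or more; the lowest counts came without a conditioned medium library, when the more variable control pair set the spread. Without a control library the less variable conditioned medium pair alone set the spread. Calls gained there, as for Cd68, Cdh5 and the Notch list, rest on the spread of that pair. DESeq2 gave 868 calls, 433 higher and 435 lower, 44 of them by 2-fold or more, all 868 among the 2330; the cause was not tested. glmTreat against a fold of 1.2 called 301 genes, more because it asks for a lower fold. The lists called fell from 12 to 0 with an estimated correlation and to 2 with fry, and numbered 11 to 13 elsewhere. A replicate block called 2671 genes, 164 by 2-fold or more, and 11 lists, losing the angiogenesis list (adjusted p = 0.0715); the numbers do not pair the libraries, whose same-number deviations had a correlation of -0.01.

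Of 103 named genes called, 33 and 35 lost the call without conditioned medium replicates 1 and 2, 7 without each control, and 25 in DESeq2. Of 22 genes named afterwards, 7 lost it without each conditioned medium library and 1 without each control. DESeq2 gave no adjusted p for Cstdc4, Gm4924, Ccl4, C4b, Ptgis, Mmp10 and Krt19, so it neither kept nor lost these calls. Of the 2330 genes called, 2208 had an adjusted p in DESeq2. No called gene or list changed sign. Some that were not called did, and the cause was not tested. With libraries left out in turn the median ranged from -0.012 to 0.015 for cell death regulators, -0.036 to 0.16 for cytokines, -0.056 to 0.068 for oxidative phosphorylation, -0.043 to 0.075 for the unfolded protein response and -0.071 to 0.092 for NF-kB genes, and the log2 fold change from -0.048 to 0.066 for Vcam1, -0.77 to 0.030 for Il6, -0.071 to 0.37 for Tnfaip3, -0.017 to 0.018 for Pecam1 and -0.018 to 0.16 for Cd68. The cell death median was 0.013 by upper quartile, 0.0065 by library total, 0.011 unfiltered and 0.00078 at 1 CPM, where the cytokine median was -0.0093. Thinned counts gave -0.018 for NF-kB genes and -0.00056 for Pecam1, which was -0.00041 without unmatched genes and -0.0022 in DESeq2. In simulated data at these depths, with the same spread in both groups, 60% of the smallest folds tried and 74% of 1.5-fold changes were called.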

Other observations

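The genes and groups in this part were chosen after their values were seen, and so were the tests on paralogs, culture differences, oxygen, macrophage RNA and granulocyte RNA; the tests on GC content and length were not, though the rule for reading the intervals of the GC, length and paralog tests was. The smallest p in the comparison belonged to Psg22, a pregnancy-specific glycoprotein gene, which rose from 223 ± 5.73 to 512 ± 17.2 CPM, 2.30-fold (edgeR adjusted p = 5.50e-13). Sema3a and Sema3f, secreted guidance cues, rose by 1.14 ± 0.07 and 0.55 ± 0.05, and Cldn15, a claudin, by 1.04 ± 0.07. Selenop, a selenium transport protein, fell by 0.83 ± 0.04, Igf1 by 0.68 ± 0.05, and Kit, a receptor tyrosine kinase, by 0.57 ± 0.05. Txnip, which restrains glucose uptake, fell from 831 ± 80.9 to 527 ± 19.2 CPM (-0.66 ± 0.05), and its relative Arrdc4 fell by 0.97 ± 0.19 (edgeR adjusted p = 0.00142; 0.0764 without conditioned medium replicate 2, from 4.62e-05 to 0.0764 over its alternatives).

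Of 11 tested genes of the interferon-inducible p200 family, DNA sensors and their relatives, 6 fell and the other 5 were not called by edgeR, with a median log2 fold change of -0.36. Ifi211 was at -0.69 ± 0.05, Mndal at -0.65 ± 0.06 and Ifi204 at -0.61 ± 0.05; these genes lie in a cluster of similar copies, so single values are uncertain. From a list of 10 cornified envelope, keratin and stefin genes drawn up because some of them rose, the 7 tested rose with a median of 2.47 at low counts, while Stfa1, Cstdc5 and Cstdc6 were below the count filter, at 5, 2 and 1 counts over the control libraries against 7, 3 and 1. Sprr2a1 and Sprr2a2 carried the same 2, 6, 41 and 71 counts, as genes that share their reads would, and Krt19 had 11 and 13 control counts against 64 and 82.

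Type I interferon-stimulated genes were lower in conditioned medium, with a median log2 fold change of -0.48 over 28 members. The trend of fold change on GC content and transcript length held 8.98% of the variance over 12465 genes. Removing it left a median of -0.48 (95% bootstrap interval -0.59 to -0.40), against the -0.2 that this trend as the cause would leave at the lowest. Here and for the glycolysis list the bootstrap resampled members as if independent, so its intervals cover scatter among genes and not between libraries. Members with no family copy in the list had a median of -0.46 (interval -0.55 to -0.26 over 18 genes), also below the -0.2 that reads shared between paralogs would allow, though the interval reaches above the bound of -0.3 set for ruling it out, which would have left the test undecided, so this argues against shared reads as the whole cause and no more. In 24 of 28 members both treated libraries lay below both controls, and since each group had its own medium, a difference in culture other than the supernatant cannot be told apart from the treatment. A response to the supernatant is thus a hypothesis that these libraries leave open.

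Glycolysis and hypoxia genes were higher in conditioned medium, with a median of 0.30. After the same removal the median was 0.26 (interval 0.19 to 0.34 over 27 genes), above the 0.1 that GC content and length as the cause would leave, but the interval reaches below the 0.2 set for ruling it out, so this test too argues only against that trend as the whole cause. Of 14 oxygen-responsive genes outside glycolysis 10 were called higher, but 12 of the 14 belong to the list whose rise prompted the test, so it is void. Of the 2 outside the list, Vegfa rose (0.58 ± 0.07) and Adm fell (-0.26 ± 0.05; not called by DESeq2 or without either treated library, adjusted p 3.04e-04 to 0.0866 over its alternatives). Lower oxygen or used-up medium in the treated cultures cannot be told apart from a response to macrophage products. No library analysed here received medium used by cells other than these macrophages.

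S100a8 was higher in conditioned medium (2.01 ± 0.15; not called with a robust estimate of the spread), as were Cxcr2, Pglyrp1 and Havcr2 (1.03 ± 0.09), all picked because they rose. Macrophage RNA or cells carried over with the supernatant would bring abundant macrophage transcripts, but the sum of 14 such genes was 5.14 CPM in control and 5.12 CPM in conditioned medium. This was a change of -0.073% of the S100a8 rise (within -1.50% to 1.35% at 2 SE of the sum) and -0.127% of the 17.0 CPM rise of Cxcr2, the smallest of the other 3 (-2.61% to 2.36%). Of the 14 genes 1 passed the count filter. The sum leaves out Cd68, which was abundant in both groups (234 ± 20.0 and 245 ± 5.76 CPM) and not called, and whose spread is too wide to decide. Granulocyte RNA would bring S100a9, whose rise was 2.81% of that of S100a8 (0.589% to 5.03%) and 4.89% of that of Cxcr2 (1.03% to 8.75%). With 2 libraries per group such ranges at 2 SE understate the uncertainty, and they leave out the error of the S100a8 and Cxcr2 rises. However, S100a9 went from 2 to 30 counts and Ly6g from 1 to 18 over the 2 libraries of each group. Other granulocyte markers did not follow: Camp went from 8 to 3 counts, Ngp from 1 to 0 and Elane from 0 to 1. Retnlg, Csf3r and Mpo had 0 counts in all 4 libraries. The markers without S100a9 and Ltf, with Ly6g among them, summed to 0.340 CPM in control and 0.705 CPM in conditioned medium. Ltf, the granulocyte marker that passed the filter, was at 0.35 ± 0.23 and not called. The summed macrophage transcripts and the S100a9 shares argue against both as the whole source of the rise of these 4 genes. A trace of granulocyte RNA stays open. Expression by the endothelial cells themselves may account for the rise, as a hypothesis with no test of its own here.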
